A study of Mus musculus with 12 samples.

How the data were processed

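Liver RNA of control and CDAHFD mice at 1, 2 and 6 weeks was hybridised to 12 arrays, 2 per group, with 150 ng of RNA labelled with Cy3 per the labels' protocols. Groups and replicate numbers were taken from the labels. Slide 1 held the arrays of weeks 1 and 2 and slide 2 those of week 6.

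The deposited values are spot intensities on a linear scale from Agilent Feature Extraction, background-subtracted and spatially detrended within each array and not normalized between arrays, per the file headers. The headers give version 11.5.1.1 of that software and the submitters' processing notes version 10.7, so the version is unsettled. Each array held 62976 spots, of which 59305 were gene spots of 55681 probes, and 0 were saturated. Spots marked as outliers by the software and control spots were left out, which left 54 values missing, and spots of 1 probe were averaged. Probe accessions were matched, without version numbers, to the RefSeq table of assembly GRCm38.p6, used for names only since the array was designed on an older build, and its coordinates were not used. This named 28664 probes with 21613 symbols and left 27017 probes unnamed. The precision is limited by the number of arrays.

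Processed intensities were taken as log2 and each array's 75th percentile was subtracted. The percentile was taken over the 20137 probes well above background on all arrays, since fewer than 50% of probes were detected on 10 of the 12 arrays, and the percentile over all probes was an added alternative. A gene was kept where a probe was well above background on both arrays of at least 1 group, and was read by its probe with the highest mean, which gave 13889 genes, 4597 of them with further probes. In 51, 31 and 29 genes at 1, 2 and 6 weeks, other probes of the gene were called in the opposite direction, of 3609 compared. Of the genes, 11390 were well above background on all arrays. No pair of replicates held identical values (0 probes in each group).

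Differences were tested with limma (lmFit and eBayes with trend and robust), 2-sided, on 6 group means over all 12 arrays, which left 6 residual degrees of freedom, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Adjusted p printed beside genes come from this limma fit. The comparisons were diet at each week, the average over weeks, the change of the diet difference between weeks by F test, 6 weeks minus 1 week, and weeks within each diet by F test. Groups of 2 are too small for a test for outlying samples. Differences of genes and lists are given relative to the median of all genes, which was 0.13, 0.05, 0.04 and 0.08 at 1, 2 and 6 weeks and in the average, with the standard error of the fit.

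A gene below background on each array of a group has only a bound there. Its fold, written as at least N-fold, sets the mean of the brighter group against, on each array of the dimmer group, the higher of the lowest signal of probes well above background and the gene's own. Genes were ranked as fitted, bounded or not, and no fold is given where both groups were below background. List medians "at bounds" take such genes at their bound, given where this moved them by at least 0.1. Of 85 called list results, 0 changed sign at bounds, and the largest move was 0.98.

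The 41 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, from general knowledge of mouse liver and steatohepatitis. Of 1003 symbols written, 1001 were matched and 907 were measured. Lists were tested with camera with a preset correlation of 0.01, with camera with an estimated correlation, and with fry, adjusted over the lists of a comparison. Camera compares a list with all other genes, while fry tests whether its genes move, on balance, one way, and does not compare them with other genes. Lists share members: lipid-associated macrophage markers share 3 with lipid droplet genes, for example. The week at which each list is described was chosen after its values were seen, and the plot of all lists shows every week. The week of description does not mark when a list first moved.

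Named genes were, at each week, the 8 called genes with the largest difference in each direction, without unnamed clones, and the 5 in each direction for the average and for 6 weeks minus 1 week. For each list they were its 3 anchors where measured, whatever they showed, and up to 4 members with the smallest adjusted p, from which examples are given. Some genes that the rule names are not reported here. For weeks within the control diet they were the 5 with the smallest adjusted p.

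Settings tried in turn, chosen in advance, were median centring, quantile normalization, normexp with an offset of 50 followed by the 75th percentile, no filter or a filter on all arrays, the mean of a gene's probes, eBayes without trend, array weights, the replicate number as a block, only the arrays of a week, a 2-fold threshold, and leaving out each array. Normexp used the median signals and median backgrounds of the spots, since the mean signal is not among the columns of the files used here. In fits without 1 array the lone sample left in its group is assumed to vary like the other groups. Chosen after seeing the data were the percentile over all probes, the masking of 17 dim blocks on 1 array with 2014 probes, fits within slide 1, unnamed probes as features, later controls at 1 week, and fits without the 1-week arrays. A term for slide is a combination of the group terms, as the rank was 6 with and without it, so slide and week 6 cannot be told apart.

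Fits were tested on 13889 simulated genes, 66 or 67 changed at each fold, fewer than called in the data. For the diet difference at 1 week 20.9, 53.7 and 87.9% of changes of 1.5-, 2- and 4-fold were recovered, and for 6 weeks minus 1 week 2.99, 19.4 and 68.2%. A first scaling test failed since it compared array medians, which the scaling does not set, and was replaced by one on the 75th percentile. Among 41 simulated lists, of which a single list was shifted, 0 of those without a shift were called by camera or fry. Genes were simulated uncorrelated, so this does not test the preset correlation. Software was R 4.3.3, limma 3.58.1, the package data.table at version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.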

Results

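Liver RNA of male C57BL/6NJcl mice was measured on 12 one-colour Agilent arrays. Mice received a standard chow (control) or CDAHFD, a choline-deficient diet with 0.1% methionine and 60 kcal% fat that is used to induce steatohepatitis. Livers were taken after 1, 2 or 6 weeks, at 7, 8 and 12 weeks of age. Each of the 6 groups held 2 arrays, so every value below rests on n = 2 per group, and this number limits the precision. The labels do not say that replicates came from separate mice, and p-values then measure only the spread between these arrays, which may be technical. On control arrays 41.6 to 45.7% of probes were well above background, and on CDAHFD arrays 46.9 to 50.9%.

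Along the first principal component, which held 64.7% of the variance, the 6 CDAHFD arrays lay apart from the 6 control arrays. The second component, with 14.8%, was set by a single array, control replicate 1 at 1 week, at 82.1, where the highest of the other arrays was at 4.87. In a corner of that array, 286 bright spots read at least 8-fold below every other array, and the probes of the dim blocks served 558 of the 13889 genes tested. The 2 arrays of the 1-week controls differed from each other by an SD of 0.85 log2 over genes, against 0.29 to 0.49 in the other groups.

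**Figure D1:**
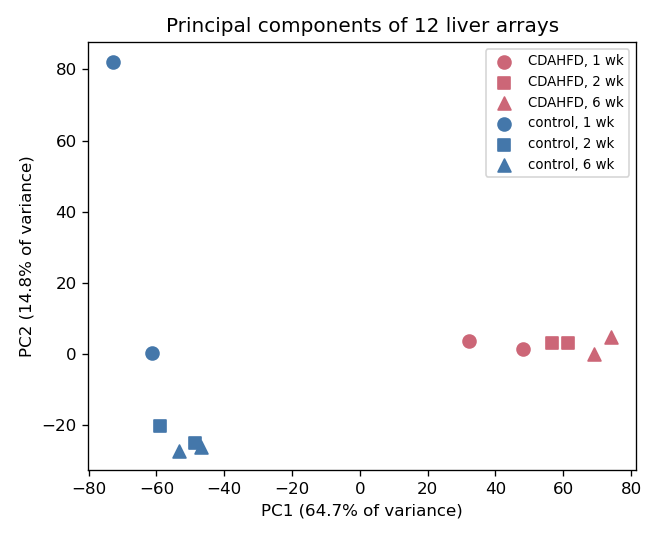
Each point is 1 array, placed by its scores on the first and second principal components of the normalized log2 values, with colour for diet and marker for week. The diets separate along the first component, and control replicate 1 at 1 week lies apart at 82.1 on the second.

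After 1 week of CDAHFD, Fgf21 (7.17 ± 0.64, above background on 1 of 2 control arrays), a hormone that the liver secretes under nutrient stress, Itgax (5.5 ± 0.34, above background on 1 of 2 control arrays), the CD11c integrin of dendritic cells and macrophages, and Nrg1 (5.41 ± 0.77, above background on 1 of 2 control arrays), a ligand of ErbB receptors, rose, measured on both diets, though Nrg1 was at 4.10 with the dim spots of control replicate 1 masked. Values in parentheses are log2 differences, CDAHFD minus control, relative to the median of all genes, with the standard error of the fit. Below background on the control arrays were Gpnmb (at least 51.9-fold higher, adjusted p = 1.2e-06), a glycoprotein of lipid-laden macrophages, and the metalloproteinase inhibitor Timp1 (at least 32.9-fold higher, adjusted p = 2.9e-06). So were the myeloid lectin Clec4d (at least 35.0-fold higher, adjusted p = 1.4e-06), the cytokine-induced ubiquitin-like protein Ubd (at least 49.6-fold higher, adjusted p = 0.00173) and the monocyte attractant Ccl7 (at least 15.0-fold higher, adjusted p = 1.7e-05). Scd1 (-6.61 ± 0.98), the stearoyl-CoA desaturase, Slc13a2 (-4.46 ± 0.21), a dicarboxylate transporter, and Elovl3 (-4.17 ± 0.46), a fatty acid elongase, fell. Ces2a (-3.32 ± 0.21), a carboxylesterase, Cyp4a12b (-3.27 ± 0.23) and Cyp3a41b (-3.23 ± 0.22), both P450 enzymes, and Hnf4aos (-3.23 ± 0.59), an antisense transcript of Hnf4a, also fell. Moxd1 (at least 9.60-fold lower, adjusted p = 1.0e-04), a monooxygenase-like gene, fell below background on CDAHFD, but was above background on 0 of 2 control arrays at 2 weeks and 1 of 2 at 6 weeks. Fgf21 was at 6.51 or 7.85 and Nrg1 at 4.09 or 6.76 without control replicate 1 or 2 at 1 week. Moxd1 was at least 6.14- or 15.0-fold lower without control replicate 1 or 2 at 1 week. Against the controls of 2 and 6 weeks, Fgf21 was at 6.29, Itgax at 4.58 and Nrg1 at 3.88.

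Inflammatory cytokines and chemokines rose at 1 week: 23 of 25 measured members were higher and 0 lower, or 23 and 0 adjusted over the list alone. Their median was 1.72, or 1.55 at bounds, with camera adjusted p = 2.4e-08 and adjusted p = 0.217 with an estimated correlation. The anchors, the first members of each list, were Ccl2 (4.47 ± 0.41), which attracts monocytes, Tnf (at least 1.73-fold higher, adjusted p = 4.2e-04), and Cxcl10 (2.38 ± 0.32), which attracts T cells, and Cxcl14 (1.53 ± 0.16) rose as well. Ccl2, Tnf and Nrg1 are read by probes in the dim blocks of control replicate 1, and with those spots masked their adjusted p was 9.4e-06, 7.4e-04 and 2.7e-05, with Ccl2 at 5.08. Dendritic cell markers had 16 members higher and 1 lower of 21 measured, or 17 and 2 adjusted over the list alone. The median lay at 1.66, with camera adjusted p = 2.8e-05 and adjusted p = 0.248 with an estimated correlation. Their anchors Clec9a (at least 7.93-fold higher, adjusted p = 1.0e-05) and Cd209a (at least 2.71-fold higher, adjusted p = 0.00208), both lectins of dendritic cells, rose with the activation marker Cd83 (2.27 ± 0.21) and the homing receptor Ccr7 (2.27 ± 0.24). B and plasma cell markers moved up as a list, with 10 members higher and 1 lower of 16 measured, or 11 and 1 adjusted over the list alone. As a list they had a median of 1.07, with camera adjusted p = 0.0206 and adjusted p = 0.270 with an estimated correlation. With normexp the median was -0.08 (adjusted p = 0.997), and the call ended against the controls of 2 and 6 weeks (adjusted p = 0.0611). Of their anchors, Ms4a1 (1.74 ± 0.37, above background on 1 of 2 control arrays), CD20, was higher, and the adaptor Blnk (2.62 ± 0.29) rose. With normexp the direction turned for Tnf (-0.07, adjusted p = 0.490). Cd209a was not called with normexp (adjusted p = 0.791). Ms4a1 was not called with normexp or the controls of 2 and 6 weeks (adjusted p = 0.806 and 0.0586). Ccl2 was at 5.07 or 3.88 without control replicate 1 or 2 at 1 week. Against the controls of 2 and 6 weeks, Ms4a1 was at 0.81.

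Erythroid markers fell at 1 week: 0 of 11 measured members were higher and 7 lower, or 0 and 7 adjusted over the list alone. The median of the list was -1.09, with camera adjusted p = 5.0e-05 and adjusted p = 0.156 with an estimated correlation. The anchors were the alpha and beta globins Hba-a1 (-1.73 ± 0.24) and Hbb-b1 (-1.95 ± 0.22) and the erythroid haem synthesis enzyme Alas2 (-1.60 ± 0.16), and the globins Hba-a2 (-1.82 ± 0.19) and Hbb-bt (-1.92 ± 0.22) fell with them.

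Hepatocyte genes fell in the same week. For hepatocyte identity, the list median was -0.96, with camera adjusted p = 2.4e-08 and adjusted p = 0.217 with an estimated correlation. In it, 0 of 23 measured members were higher and 18 lower, or 0 and 18 adjusted over the list alone. Its anchors Alb (-1.30 ± 0.18), serum albumin, Hnf4a (-0.78 ± 0.11), a nuclear receptor that maintains hepatocyte genes, and Ttr (-1.22 ± 0.19), transthyretin, fell, as did prothrombin, F2 (-1.0 ± 0.13). In cytochrome P450 drug metabolism, 1 of 25 measured members were higher and 14 lower, or 3 and 15 adjusted over the list alone. The median difference was -1.0, with camera adjusted p = 4.7e-05 and adjusted p = 0.243 with an estimated correlation. Here Cyp3a11 (-2.48 ± 0.17), an inducible P450 of xenobiotic metabolism, and Cyp2e1 (-1.0 ± 0.16), which oxidises ethanol, fell, whereas Cyp1a2 (-0.07 ± 0.18) did not pass, and the fatty acid hydroxylase Cyp4a12a (-3.12 ± 0.22) fell. Choline, methionine and one-carbon metabolism, which draws on nutrients that the diet lacks, had 3 members higher and 12 lower of 24 measured, or 3 and 12 adjusted over the list alone. Members had a median of -0.75, with camera adjusted p = 0.00131 and adjusted p = 0.284 with an estimated correlation, a call that ended with normexp (adjusted p = 0.0989). Its anchors Pemt (-0.73 ± 0.14), which methylates phosphatidylethanolamine to phosphatidylcholine, Bhmt (-1.20 ± 0.14), which uses betaine to remethylate homocysteine, and Gnmt (-1.95 ± 0.23), which consumes S-adenosylmethionine, fell, while Mat2a (1.72 ± 0.10), a methionine adenosyltransferase, rose. At 1 week the median difference was 0.57 among genes with the dimmest probes and -0.57 among those with the brightest. Set against random lists matched on signal, the medians of hepatocyte identity, P450 and one-carbon genes lay at -0.48, -0.63 and -0.46. Alb and F2 were not called with the controls of 2 and 6 weeks (adjusted p = 0.843 and 0.113). Hnf4a and Bhmt were not called with quantile normalization (adjusted p = 0.485 and 0.158). Cyp2e1 was not called with the controls of 2 and 6 weeks or quantile normalization (adjusted p = 0.0577 and 0.640). Pemt was not called with quantile normalization (adjusted p = 0.415), nor without CDAHFD replicate 1 at 1 week (adjusted p = 0.0674). Against the controls of 2 and 6 weeks, Alb was at -0.01, Ttr at -0.54, F2 at -0.32 and Mat2a at 0.92.

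In total, 5684 of 13889 genes changed at 1 week, 3603 higher and 2081 lower, and 2436 of them at least 2-fold. The count fell to 3072 without CDAHFD replicate 1 at 1 week, and it was 4894 when the later controls replaced those of 1 week, a choice made after the data were seen. Of the 5684 genes, 3443 then kept their call and direction and 35 were called the opposite way. The share of higher calls was 63.4%, but 45.6% with median centring, 33.2% with normexp and 36.1% with the percentile taken over all probes, settings that moved the median of all genes by -0.18, -0.33 and -0.29.

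After 2 weeks, genes that rose and were measured on both diets were Ubd (7.51 ± 0.85, above background on 1 of 2 control arrays), Lcn2 (6.67 ± 0.21), an iron-siderophore binding protein of the acute phase, Ly6d (6.58 ± 0.36), a GPI-anchored surface protein, and Adam8 (6.52 ± 0.27, above background on 1 of 2 control arrays), a metalloprotease of leukocytes. Gpnmb (at least 192-fold higher, adjusted p = 8.1e-08), Timp1 (at least 35.6-fold higher, adjusted p = 4.9e-07) and Vsig8 (at least 79.6-fold higher, adjusted p = 4.0e-07), an immunoglobulin-domain protein, were below background in controls. So was Sprr1a (at least 38.9-fold higher, adjusted p = 3.7e-05), a small proline-rich protein of squamous epithelium. Scd1 (-5.68 ± 0.98), Elovl3 (-5.45 ± 0.46) and Slc13a2 (-4.52 ± 0.21) again fell steeply. Ces2a (-3.57 ± 0.21), Cyp2c38 (-3.64 ± 0.23), a P450, Adgrf1 (-3.58 ± 0.31), an adhesion receptor, Serpina4-ps1 (-3.90 ± 0.85), a serpin pseudogene, and Hsd3b5 (-4.23 ± 1.18), a steroid dehydrogenase of male mouse liver, fell too. Serpina4-ps1 was not called without control replicate 1 at 2 weeks (adjusted p = 0.0642) or CDAHFD replicate 1 at 2 weeks (adjusted p = 0.0727). Hsd3b5 was not called without CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0564 and 0.0563), control replicate 1 or 2 at 2 weeks (adjusted p = 0.120 and 0.0997), CDAHFD replicate 1 or 2 at 2 weeks (adjusted p = 0.137 and 0.101) or control replicate 1 or 2 at 6 weeks (adjusted p = 0.0575 and 0.0575). Ubd was at 6.28 or 8.74 and Serpina4-ps1 at -3.01 or -4.80 without control replicate 1 or 2 at 2 weeks. Another probe was at -1.05 for Cyp2c38.

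Macrophage and monocyte markers rose at 2 weeks: 27 of 29 measured members were higher and 0 lower, or 27 and 0 adjusted over the list alone. In the median they were at 2.12, with camera adjusted p = 1.7e-11 and adjusted p = 0.206 with an estimated correlation. The measured anchors Adgre1 (1.58 ± 0.39), the F4/80 antigen, and Cd68 (3.04 ± 0.18), a lysosomal protein of macrophages, rose, as did the chemokine receptor Cx3cr1 (4.53 ± 0.20, above background on 1 of 2 control arrays) and the galectin Lgals3 (4.59 ± 0.31). Markers of lipid-associated macrophages had 19 members higher and 1 lower of 24 measured, or 20 and 1 adjusted over the list alone. Their median was 1.95, or 1.76 at bounds, with camera adjusted p = 2.6e-10 and adjusted p = 0.127 with an estimated correlation. Next to Gpnmb, their anchors Trem2 (6.34 ± 0.21), a lipid-sensing receptor, and Spp1 (2.17 ± 0.24), osteopontin, rose with the tetraspanin Cd63 (3.90 ± 0.17). T and NK cell markers showed 15 members higher and 1 lower of 26 measured, or 15 and 1 adjusted over the list alone. The median lay at 1.05, or 0.80 at bounds, with camera adjusted p = 0.00305 and adjusted p = 0.355 with an estimated correlation, a call that ended with normexp (adjusted p = 0.31). Neither measured anchor, Cd3e (-0.31 ± 0.21), a subunit of the T cell receptor complex, or Nkg7 (0.17 ± 0.17), a granule protein of cytotoxic cells, passed, while the interleukin 7 receptor, Il7r (at least 9.0-fold higher, adjusted p = 4.4e-05), and the NK receptor Klrd1 (at least 6.34-fold higher, adjusted p = 7.2e-05) rose. Klrd1 was not called with normexp (adjusted p = 0.0502). Adgre1 was not called without CDAHFD replicate 2 at 2 weeks (adjusted p = 0.0656). Adgre1 was at 0.96 or 2.19 without control replicate 1 or 2 at 2 weeks.

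Cell cycle genes rose at 2 weeks: 31 of 34 measured members were higher and 1 lower, or 31 and 1 adjusted over the list alone. As a list they had a median of 2.52, or 2.41 at bounds, with camera adjusted p = 6.2e-11 and adjusted p = 0.218 with an estimated correlation. Their anchors were Mki67 (3.12 ± 0.29), a proliferation antigen, Ccnb1 (at least 8.16-fold higher, adjusted p = 1.6e-04), cyclin B1, and Top2a (at least 3.82-fold higher, adjusted p = 2.7e-04), a topoisomerase, and cyclin B2, Ccnb2 (3.03 ± 0.27), rose as well. For p53 targets and senescence, the list median was 0.66, with camera adjusted p = 6.5e-05 and adjusted p = 0.127 with an estimated correlation. In it, 13 of 21 measured members were higher and 0 lower, or 13 and 0 adjusted over the list alone. The cell cycle inhibitor Cdkn1a (2.75 ± 0.43) and the p53 ligase Mdm2 (0.56 ± 0.13) rose, as did Phlda3 (3.06 ± 0.22), a p53-induced inhibitor of Akt. Cdkn2a, below background in controls, did not pass (adjusted p = 0.879). In apoptosis and necroptosis, 12 of 20 measured members were higher and 1 lower, or 12 and 1 adjusted over the list alone. List members had a median of 0.61, with camera adjusted p = 6.1e-04 and adjusted p = 0.20 with an estimated correlation. The necroptosis kinase Ripk3 (2.16 ± 0.30) and its effector Mlkl (1.73 ± 0.23) rose with Tnfrsf12a (2.28 ± 0.16), the TWEAK receptor, and Casp8 (0.18 ± 1.1), read by a probe in the dim blocks of the 1-week control array, did not pass. Top2a was not called with normexp (adjusted p = 0.301). Another probe was at 1.36 for Cdkn1a. The other 2 probes were at 2.10 and 2.56 for Ccnb1.

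Urea cycle and amino acid breakdown fell at 2 weeks: 0 of 23 measured members were higher and 16 lower, or 0 and 20 adjusted over the list alone. The median difference was -0.98, with camera adjusted p = 2.1e-09 and adjusted p = 0.127 with an estimated correlation. The urea cycle anchors Cps1 (-1.01 ± 0.21), Otc (-1.17 ± 0.09) and Arg1 (-0.84 ± 0.14) fell with the liver glutaminase Gls2 (-1.61 ± 0.13). Oxidative phosphorylation had 0 members higher and 20 lower of 30 measured, or 0 and 23 adjusted over the list alone. Members had a median of -0.55, with camera adjusted p = 7.3e-09 and adjusted p = 0.20 with an estimated correlation. The respiratory chain subunits Ndufb8 (-0.72 ± 0.12), Cox4i1 (-0.59 ± 0.15) and Ndufb5 (-1.10 ± 0.12) fell, and Ndufa1 (-0.48 ± 3.32), read by a probe in the dim blocks, did not pass. Against lists matched on signal the urea cycle median lay at -0.64, and that of oxidative phosphorylation at -0.14, the 9.80th percentile, within their range. Lipoprotein assembly and secretion was not called at 2 weeks, with 4 members higher and 8 lower of 16 measured, or 4 and 8 adjusted over the list alone. In the median they were at -0.57, with camera adjusted p = 0.116. At 1 week it fell (median -0.64, camera adjusted p = 0.0278, adjusted p = 0.353 with an estimated correlation), but not with median centring, quantile normalization, normexp, the percentile over all probes, no filter on dim probes or the later controls, or without control replicate 2 at 1 week (adjusted p = 0.0634 to 0.727). Its anchors at 2 weeks Mttp (-0.58 ± 0.13), which loads lipid onto apolipoprotein B, and Apob (-0.72 ± 0.17) were lower and Apoa1 (-0.37 ± 0.16) did not pass, while Apoa4 (4.93 ± 0.39) and the sterol exporter Abcg1 (2.07 ± 0.21) rose. Acute phase and complement genes were not called at 2 weeks either, with 9 members higher and 7 lower of 27 measured, or 10 and 9 adjusted over the list alone. Their median was -0.27, with camera adjusted p = 0.948. The mean, 0.44, lay above 0, unlike the median, and quantile normalization turned the median to 0.45 (adjusted p = 0.011). The anchors Saa1 (2.38 ± 0.36) and Saa2 (1.5 ± 0.31), both serum amyloids, and Lcn2 rose, and fibrinogen alpha, Fga (-1.10 ± 0.12), fell. With quantile normalization the direction turned for Cox4i1 (0.00287, adjusted p = 0.962). Apob was not called with quantile normalization or the mean of a gene's probes (adjusted p = 0.141 and 0.103), nor without control replicate 1 at 2 weeks (adjusted p = 0.0778) or CDAHFD replicate 2 at 2 weeks (adjusted p = 0.0714). Cox4i1 was not called without control replicate 1 at 2 weeks (adjusted p = 0.116) or CDAHFD replicate 2 at 2 weeks (adjusted p = 0.108). Mttp was not called without control replicate 1 at 2 weeks (adjusted p = 0.0593) or CDAHFD replicate 2 at 2 weeks (adjusted p = 0.0641). Ndufa1 was called with the defect masked (adjusted p = 0.0171), or without control replicate 1 or 2 at 1 week (adjusted p = 0.0181 and 0.0171). Apoa1 was called with the percentile over all probes (adjusted p = 0.0324), or without CDAHFD replicate 1 or 2 at 6 weeks (adjusted p = 0.0447 and 0.0449). Another probe was at 0.04 for Ndufb5.

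At 2 weeks 5256 genes changed, 3181 higher and 2075 lower, with 2461 of them at least 2-fold. Without CDAHFD replicate 2 at 2 weeks the count was 3389, and with normexp 3426. Higher genes made up 60.5% of the calls, 49.0% with median centring, 48.2% with normexp and 39.3% with the percentile over all probes, which moved the median of all genes by -0.11, -0.20 and -0.21.

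After 6 weeks Trem2 (7.43 ± 0.21), Adam8 (6.99 ± 0.27) and Ly6d (6.68 ± 0.36) rose, measured on both diets. Below background in controls were Gpnmb (at least 405-fold higher, adjusted p = 2.4e-08), Vsig8 (at least 93.2-fold higher, adjusted p = 2.3e-07), Timp1 (at least 36.9-fold higher, adjusted p = 2.6e-07) and Clec4d (at least 99.1-fold higher, adjusted p = 2.0e-07), and H19 (at least 74.2-fold higher, adjusted p = 3.3e-06), an imprinted long non-coding RNA of fetal liver. Hsd3b5 (-9.17 ± 1.18, above background on 1 of 2 CDAHFD arrays), Serpina4-ps1 (-6.93 ± 0.85), Dct (-6.70 ± 0.40), an enzyme known from melanin synthesis, and Scd1 (-6.35 ± 0.98) fell, as did Serpina9 (-5.42 ± 1.23, above background on 1 of 2 CDAHFD arrays), a serpin, Hnf4aos (-5.36 ± 0.59) and Slc13a2 (-5.20 ± 0.21). The olfactory receptor gene Olfr125 (at least 8.40-fold lower, adjusted p = 3.3e-06) fell below background. Serpina9 was not called without control replicate 2 at 6 weeks (adjusted p = 0.0744). H19 was at least 42.9- or 128-fold higher without CDAHFD replicate 1 or 2 at 6 weeks. Hsd3b5 was at -7.15 or -11.20, Serpina4-ps1 at -5.93 or -7.95, Scd1 at -4.74 or -7.97, Serpina9 at -3.35 or -7.51 and Hnf4aos at -6.38 or -4.36 without CDAHFD replicate 1 or 2 at 6 weeks.

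Collagens and matrix proteins rose at 6 weeks: 24 of 29 measured members were higher and 3 lower, or 25 and 3 adjusted over the list alone. The median lay at 1.70, or 1.44 at bounds, with camera adjusted p = 2.0e-08 and adjusted p = 0.191 with an estimated correlation. The fibrillar collagen anchors Col1a1 (4.01 ± 0.25) and Col3a1 (3.47 ± 0.25) rose with Col1a2 (3.37 ± 0.20) and lumican, Lum (3.04 ± 0.22), a collagen-binding proteoglycan, while fibronectin, Fn1 (-0.45 ± 0.15), which hepatocytes secrete into plasma, was lower. For matrix remodelling and TGF-beta signalling, the list median was 1.72, with camera adjusted p = 5.8e-10 and adjusted p = 0.158 with an estimated correlation. In it, 25 of 33 measured members were higher and 0 lower, or 26 and 0 adjusted over the list alone. Besides Timp1, its anchors Tgfb1 (1.62 ± 0.18) and Mmp12 (at least 29.3-fold higher, adjusted p = 2.0e-04), the macrophage elastase, rose, and so did the collagen crosslinker Loxl2 (2.31 ± 0.13) and the growth factor Pdgfb (2.89 ± 0.18). Hepatic stellate cell and myofibroblast markers, which share members with the collagen list, had 19 members higher and 1 lower of 28 measured, or 21 and 1 adjusted over the list alone. The median of the list was 1.19, with camera adjusted p = 1.6e-07 and adjusted p = 0.207 with an estimated correlation. Smooth muscle actin, Acta2 (1.87 ± 0.41), the PDGF receptor Pdgfrb (1.94 ± 0.19) and S100a6 (3.23 ± 0.15) rose, and desmin, Des (0.56 ± 0.25), did not pass. Fn1 was not called with quantile normalization, normexp, no filter on dim probes, eBayes without trend or array weights (adjusted p = 0.109, 0.124, 0.0660, 0.0744 and 0.0571), nor without CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0677 and 0.0677), control replicate 1 or 2 at 2 weeks (adjusted p = 0.0623 and 0.0622), CDAHFD replicate 1 or 2 at 2 weeks (adjusted p = 0.0631 and 0.0632), control replicate 1 or 2 at 6 weeks (adjusted p = 0.186 and 0.119) or CDAHFD replicate 2 at 6 weeks (adjusted p = 0.311). Des was called with eBayes without trend (adjusted p = 0.0207). Another probe was at 2.42 for Mmp12. The other 2 probes were at 0.80 and 1.35 for Loxl2.

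Markers of other cell types differed in direction at 6 weeks. Cholangiocyte and ductular reaction markers had 17 members higher and 0 lower of 24 measured, or 17 and 1 adjusted over the list alone. List members had a median of 1.20, or 1.07 at bounds, with camera adjusted p = 2.5e-04 and adjusted p = 0.260 with an estimated correlation. Among their anchors Epcam (1.31 ± 0.30), an epithelial adhesion molecule, rose and Krt19 (1.15 ± 0.54) and Sox9 (0.06 ± 0.23) did not pass, while osteopontin, Spp1 (2.77 ± 0.24), and the annexin Anxa4 (0.95 ± 0.11) rose. Liver sinusoidal endothelial cell markers fell on balance: 4 of 29 measured members were higher and 15 lower, or 4 and 15 adjusted over the list alone. The median difference was -0.57, with camera adjusted p = 5.1e-04 and adjusted p = 0.303 with an estimated correlation. Pecam1 (-0.68 ± 0.22), the adhesion molecule CD31, was lower, Stab2 (-0.20 ± 0.12), the hyaluronan scavenger receptor, did not pass, and the hyaluronan receptor Lyve1 (1.01 ± 0.28) was higher. Dnase1l3 (-1.31 ± 0.15), a secreted nuclease, fell, and Cd34 (2.15 ± 0.22) and Plvap (1.25 ± 0.12), both known from capillary endothelium, rose. Neutrophil markers had 12 members higher and 1 lower of 18 measured, or 12 and 1 adjusted over the list alone. Members had a median of 1.54, or 0.56 at bounds, with camera adjusted p = 0.0151 and adjusted p = 0.221 with an estimated correlation, and adjusted p = 0.105 with normexp. Their anchors S100a8 (2.96 ± 0.29) and S100a9 (2.86 ± 0.33), the calgranulins, rose with Ly6c1 (1.29 ± 0.15), and Ly6g (-0.41 ± 0.21) did not pass. Epcam was not called with normexp (adjusted p = 0.581). Pecam1 was not called with normexp, no filter on dim probes or array weights (adjusted p = 0.122, 0.0622 and 0.0616), nor without CDAHFD replicate 1 or 2 at 2 weeks (adjusted p = 0.0552 and 0.0550), control replicate 1 or 2 at 6 weeks (adjusted p = 0.0520 and 0.212) or CDAHFD replicate 1 or 2 at 6 weeks (adjusted p = 0.0573 and 0.145). Lyve1 was not called without control replicate 1 at 6 weeks (adjusted p = 0.0862). Stab2 was called with the percentile over all probes (adjusted p = 0.0292). Ly6g was called with the percentile over all probes or quantile normalization (adjusted p = 0.0264 and 0.0312). Krt19 was called without CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0361 and 0.0360).

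**Figure D2:**
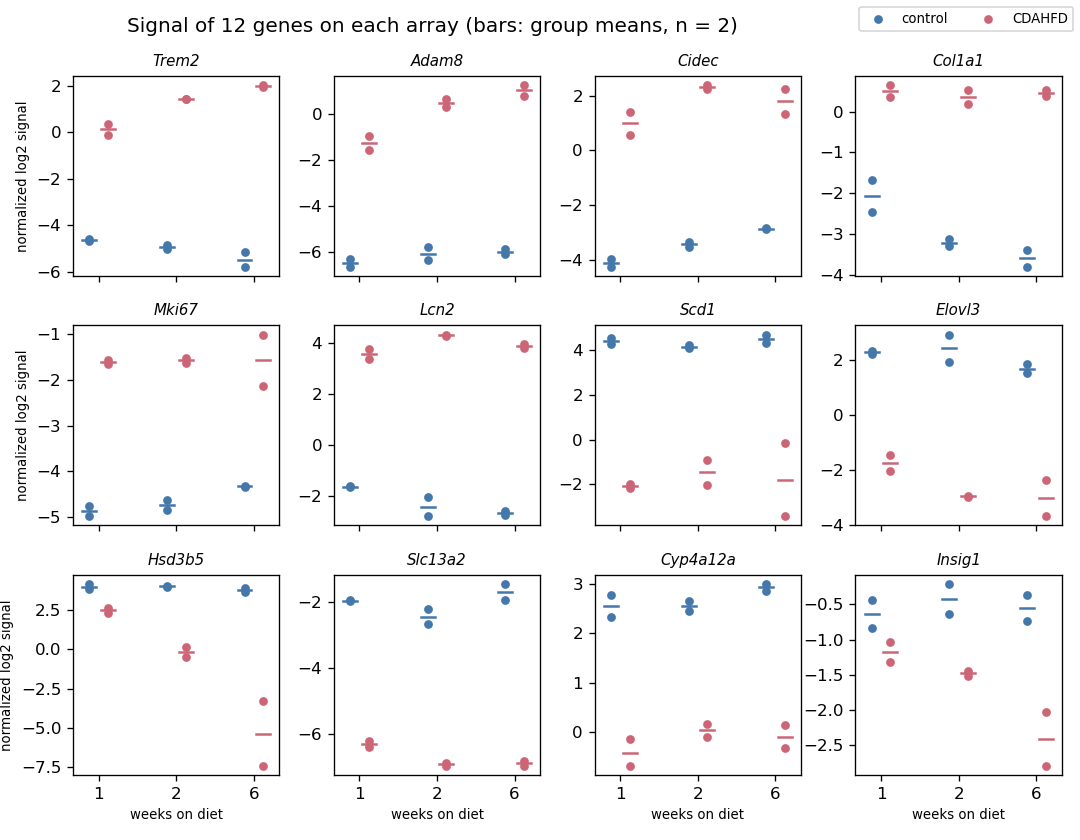
Each point is the normalized log2 signal of 1 array for 1 of 12 genes by week, in 1 colour per diet, with a bar at each mean of 2 arrays. Trem2, Adam8, Lcn2, Col1a1, Cidec and Mki67 lie higher on both CDAHFD arrays than on both control arrays at each week, and the other 6 genes lie lower.

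Sex-biased liver genes moved apart at 6 weeks. Male-biased genes fell, with 0 members higher and 20 lower of 22 measured, or 0 and 20 adjusted over the list alone. In the median they were at -2.01, or -1.72 at bounds, with camera adjusted p = 7.4e-12 and adjusted p = 0.104 with an estimated correlation. Cyp4a12a (-3.08 ± 0.22), Elovl3 (-4.77 ± 0.46) and the organic anion transporter Slco1a1 (-3.45 ± 0.23) fell, and the major urinary protein Mup20 (-0.31 ± 0.16) did not pass. Female-biased genes had 10 members higher and 2 lower of 18 measured, or 10 and 2 adjusted over the list alone. Their median was 1.45, or 1.13 at bounds, with camera adjusted p = 0.0240 and adjusted p = 0.380 with an estimated correlation, a call that ended without CDAHFD replicate 1 at 6 weeks (adjusted p = 0.144), while the median was 2.66 without replicate 2 of that group. The measured anchor Cyp2b9 (at least 7.66-fold higher, adjusted p = 4.5e-05), a female-predominant P450, rose, as did Atp6v0d2 (3.68 ± 0.41), a proton pump subunit also known from macrophages, while Cyp3a16 (-1.13 ± 0.19), another P450, fell. Mup20 was called with the percentile over all probes (adjusted p = 0.0411). Elovl3 was at -5.46 or -4.10 without CDAHFD replicate 1 or 2 at 6 weeks. Cyp2b9 was at least 4.73- or 12.4-fold higher without CDAHFD replicate 1 or 2 at 6 weeks.

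Sterol, fat and bile acid genes were lower on balance at 6 weeks. Cholesterol synthesis had 0 members higher and 15 lower of 23 measured, or 0 and 16 adjusted over the list alone. The median lay at -1.04, with camera adjusted p = 3.9e-06 and adjusted p = 0.303 with an estimated correlation. Stard4 (-1.93 ± 0.21), a sterol carrier, and Insig1 (-1.89 ± 0.26), a brake on SREBP processing, fell, while Sqle (-0.38 ± 0.51) did not pass. In fatty acid and triglyceride synthesis, 1 of 21 measured members were higher and 9 lower, or 1 and 10 adjusted over the list alone. As a list they had a median of -0.83, with camera adjusted p = 2.5e-04 and adjusted p = 0.260 with an estimated correlation. Next to Scd1, Me1 (-2.17 ± 0.20), which supplies NADPH, and Acss2 (-2.03 ± 0.20), which makes acetyl-CoA, fell, and Fasn (-1.18 ± 0.73) and Srebf1 (-0.83 ± 0.37) did not pass. Bile acid synthesis and transport showed 3 members higher and 11 lower of 22 measured, or 3 and 11 adjusted over the list alone. The median of the list was -0.71, with camera adjusted p = 0.00309 and adjusted p = 0.104 with an estimated correlation. Cyp8b1 (-2.36 ± 0.73), which makes cholic acid, was lower, and the uptake carrier Slc10a1 (-0.73 ± 0.13) and the oxysterol hydroxylase Cyp7b1 (-3.58 ± 0.32) fell. Cyp7a1 (0.25 ± 0.41), the rate-limiting enzyme of bile acid synthesis, did not pass, and the basolateral exporter subunit Slc51b (at least 5.58-fold higher, adjusted p = 3.4e-05) rose. Cyp8b1 was not called with normexp or no filter on dim probes (adjusted p = 0.0625 and 0.0607), nor without CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0633 and 0.0632), CDAHFD replicate 1 or 2 at 2 weeks (adjusted p = 0.0635 and 0.0634), control replicate 1 or 2 at 6 weeks (adjusted p = 0.126 and 0.142) or CDAHFD replicate 2 at 6 weeks (adjusted p = 0.163). Srebf1 was called with the percentile over all probes (adjusted p = 0.0447), or without CDAHFD replicate 2 at 6 weeks (adjusted p = 2.5e-04). Fasn was called without CDAHFD replicate 2 at 6 weeks (adjusted p = 0.00525). Cyp8b1 was at -3.38 or -1.36 without CDAHFD replicate 1 or 2 at 6 weeks. Another probe was at -1.89 for Slc10a1.

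Lipid droplet and lipid uptake genes had 9 members higher and 2 lower of 20 measured, or 9 and 2 adjusted over the list alone. List members had a median of 0.47, with camera adjusted p = 0.0151 and adjusted p = 0.335 with an estimated correlation, a call that ended without CDAHFD replicate 1 at 6 weeks (adjusted p = 0.077). The droplet-fusing Cidec (4.61 ± 0.31), the fatty acid translocase Cd36 (2.83 ± 0.24) and lipoprotein lipase, Lpl (3.05 ± 0.20), rose, and the droplet coat protein Plin2 (0.44 ± 0.21) did not pass. Gluconeogenesis and glycogen was not called at 6 weeks, with 2 members higher and 6 lower of 18 measured, or 2 and 7 adjusted over the list alone. The median difference was -0.33, with camera adjusted p = 0.0734. It was called without control replicate 2 or CDAHFD replicate 1 at 6 weeks. At 1 and 2 weeks it fell (medians -0.55 and -0.26, camera adjusted p = 0.0206 and 0.0372). An estimated correlation gave adjusted p = 0.315 and 0.387. Calls ended with median centring, quantile normalization, normexp, the percentile over all probes or no filter on dim probes (adjusted p = 0.0506 to 0.732). They also ended without CDAHFD replicate 1 at 1 week and control replicate 2 at 2 weeks. Against lists matched on signal medians lay at -0.12 and 0.07, within range. At 6 weeks Pck1 (0.26 ± 0.13) and G6pc (-0.68 ± 0.49) did not pass, and Fbp1 (-0.46 ± 0.13), fructose bisphosphatase, and Gpd1 (-1.23 ± 0.13) were lower. Of phase II conjugation genes, 1 of 23 measured members were higher and 11 lower, or 1 and 11 adjusted over the list alone. Members had a median of -0.51, with camera adjusted p = 2.6e-04 and adjusted p = 0.104 with an estimated correlation. Against lists matched on signal the median lay at -0.30. The anchors Gstm1 (-0.16 ± 0.17) and Sult1a1 (0.44 ± 0.30) did not pass, while the glucuronosyltransferases Ugt2b1 (-2.44 ± 0.17) and Ugt2b5 (-1.17 ± 0.11) fell. With quantile normalization the direction turned for Fbp1 (0.06, adjusted p = 0.855). Fbp1 was not called with normexp (adjusted p = 0.0585), nor without control replicate 1 at 6 weeks (adjusted p = 0.189) or CDAHFD replicate 2 at 6 weeks (adjusted p = 0.115). Pck1 was called with quantile normalization (adjusted p = 3.4e-04). Plin2 was called with quantile normalization or normexp (adjusted p = 0.0157 and 0.0160), or without CDAHFD replicate 2 at 6 weeks (adjusted p = 7.9e-04). Sult1a1 was called without CDAHFD replicate 2 at 6 weeks (adjusted p = 0.00537).

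The interferon response had 13 members higher and 0 lower of 23 measured, or 15 and 0 adjusted over the list alone. In the median they were at 0.95, with camera adjusted p = 2.7e-04 and adjusted p = 0.335 with an estimated correlation. Among its anchors Isg15 (0.67 ± 0.26) and Ifit1 (0.40 ± 0.21) did not pass, while the oligoadenylate synthetases Oas2 (2.26 ± 0.21) and Oas1a (2.04 ± 0.24) rose. Liver tumour and oncofetal genes rose, with 18 members higher and 0 lower of 19 measured, or 18 and 0 adjusted over the list alone. Their median was 1.91, or 1.70 at bounds, with camera adjusted p = 6.8e-09 and adjusted p = 0.104 with an estimated correlation. Afp (2.18 ± 0.30), alpha-fetoprotein, and Gpc3 (1.33 ± 0.40, above background on 1 of 2 control arrays), a fetal liver proteoglycan, were higher, as were the hyaluronan receptor Cd44 (2.61 ± 0.15), Ly6d and H19. Gpc3 was not called with quantile normalization or normexp (adjusted p = 0.0674 and 0.757), nor without control replicate 1 at 6 weeks (adjusted p = 0.154) or CDAHFD replicate 1 at 6 weeks (adjusted p = 0.101). Isg15 was called with the mean of a gene's probes, array weights or the defect masked (adjusted p = 0.0493, 0.0351 and 0.0481), or without CDAHFD replicate 1 at 6 weeks (adjusted p = 1.7e-04). Ifit1 was called without control replicate 1 or 2 at 2 weeks (adjusted p = 0.0277 and 0.0287).

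**Figure D3:**
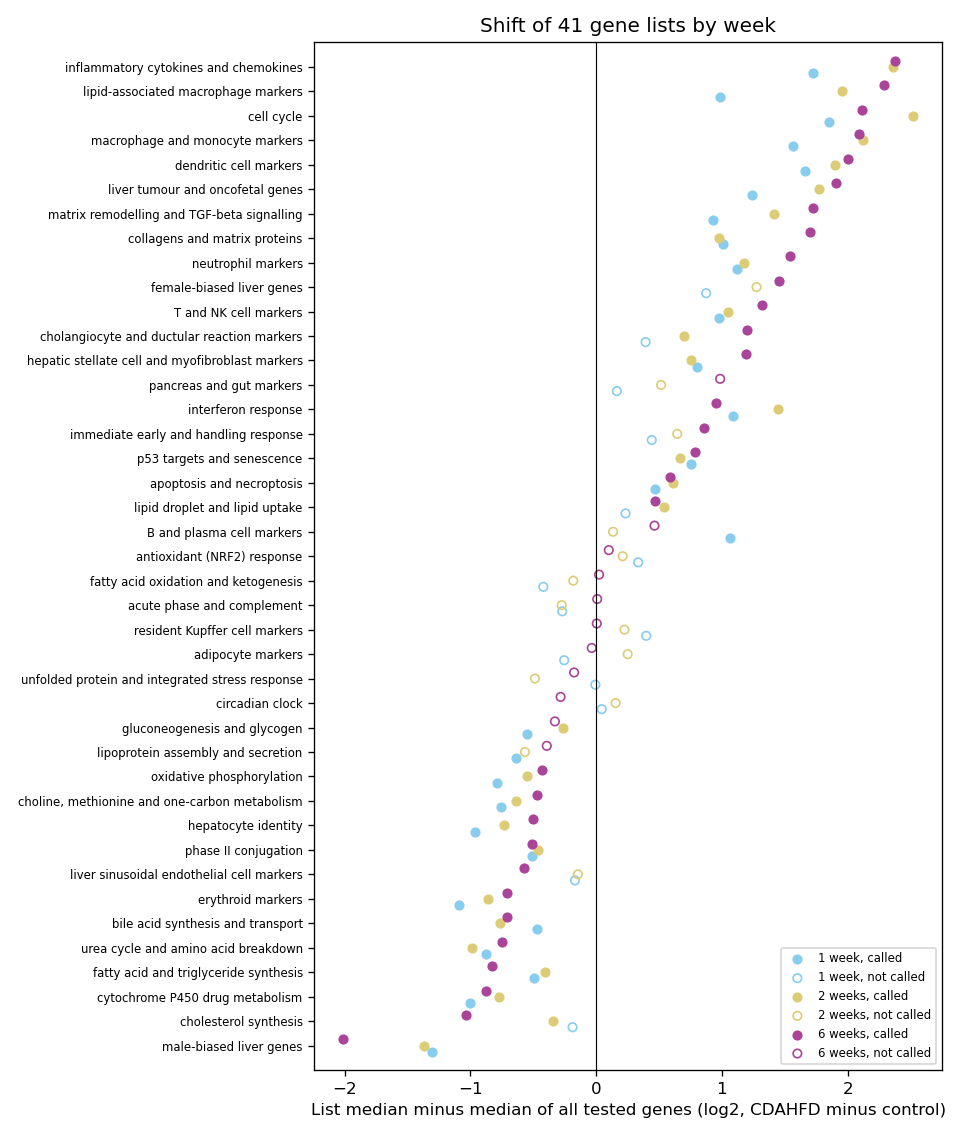
Each of 41 gene lists has 3 points, for 1, 2 and 6 weeks, at the median log2 difference of its members minus the median of all genes tested. Filled points were called by camera with the preset correlation, and none of them was called with an estimated correlation.

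At 6 weeks 5657 genes changed, 3405 higher and 2252 lower, 2775 of them at least 2-fold, and the count was 3763 with normexp. The share of higher calls was 60.2%, against 48.2% with median centring and 38.1% with the percentile over all probes, which moved the median of all genes by -0.12 and -0.24. Camera with the preset correlation called 27, 28 and 30 of the 41 lists at 1, 2 and 6 weeks. Limma's camera with an estimated correlation called 0 at each week, 8, 10 and 10 at an unadjusted p under 0.05, and fry called 31, 30 and 33.

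Averaged over weeks, 6 arrays against 6, Scd1 (-6.22 ± 0.57), Hsd3b5 (-5.01 ± 0.68), Elovl3 (-4.80 ± 0.27), Slc13a2 (-4.73 ± 0.12) and Dct (-4.14 ± 0.23) fell. Hsd3b5 was at -4.34 or -5.69 without CDAHFD replicate 1 or 2 at 6 weeks. Gpnmb (adjusted p = 5.3e-10), Clec4d (adjusted p = 2.1e-09), Timp1 (adjusted p = 3.0e-09), Vsig8 (adjusted p = 3.2e-09) and Ubd (adjusted p = 2.2e-05) were higher, and as their controls lay below background on some or all arrays no fold is given. In this average 8513 genes changed, 4943 higher and 3570 lower, 2544 of them at least 2-fold. Higher calls made up 58.1%, against 44.8% with median centring, 35.3% with normexp, 36.3% with the percentile over all probes and 41.5% with no filter on dim probes. Weeks shared a variance per gene, though no controls, so calls were not independent. At 1 and 2 weeks 2308 higher and 1271 lower genes were shared. At all 3 weeks 2109 genes were higher and 981 lower.

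To ask whether the diet difference changed with feeding time, the differences of 6 weeks and 1 week were compared. The median change over members was 0.93 for lipid-associated macrophage markers (camera adjusted p = 2.5e-11, adjusted p = 0.313 with an estimated correlation). For cholesterol synthesis it was -0.91 (camera adjusted p = 2.1e-05, adjusted p = 0.617 with an estimated correlation). It was -0.58 without control replicate 1 at 1 week or control replicate 2 at 6 weeks. Of genes above background in every group, the diet difference was more positive at 6 weeks for Ntrk2 (4.21 ± 0.53), a neurotrophin receptor, and Cib3 (3.68 ± 0.42), a calcium-binding protein, and more negative for Dct (-3.69 ± 0.56) and Serpina4-ps1 (-6.85 ± 1.20), on the log2 scale of the fit. Themis, a T cell signalling protein, Syngr1, a vesicle protein, and H19 were more positive at 6 weeks and Pdpr, Wif1 and Gbp2b more negative, and as each was below background in at least 1 group no fold is given. In all, 747 genes differed, 348 more positive and 399 more negative at 6 weeks, or 46.6% positive and 65.5% with normexp, and over the 3 weeks together 330 genes changed their diet difference. Dct was not called without CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0550 and 0.0510) or control replicate 1 at 6 weeks (adjusted p = 0.0543). Serpina4-ps1 was not called without CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0889 and 0.0892), CDAHFD replicate 1 or 2 at 2 weeks (adjusted p = 0.0590 and 0.0587) or control replicate 1 or 2 at 6 weeks (adjusted p = 0.0920 and 0.0982). Ntrk2 was at 4.88 or 3.53 and Serpina4-ps1 at -5.82 or -7.88 without CDAHFD replicate 1 or 2 at 6 weeks.

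The 330 genes became 141 without control replicate 1 at 1 week, 609 without control replicate 2 at 1 week, 27 without CDAHFD replicate 1 at 1 week, 23 without CDAHFD replicate 2 at 1 week, 80 without CDAHFD replicate 1 at 2 weeks, 84 without CDAHFD replicate 2 at 2 weeks, 55 without control replicate 1 at 6 weeks, 117 without control replicate 2 at 6 weeks and 573 without CDAHFD replicate 2 at 6 weeks. The 747 genes became 371 without control replicate 1 at 1 week, 169 without CDAHFD replicate 1 at 1 week, 188 without CDAHFD replicate 2 at 1 week, 372 without CDAHFD replicate 1 at 2 weeks, 371 without CDAHFD replicate 2 at 2 weeks, 129 without control replicate 1 at 6 weeks and 245 without control replicate 2 at 6 weeks. On the slide of weeks 1 and 2 alone, 223 genes changed their diet difference. Without the 1-week arrays, 0 genes differed between 2 and 6 weeks by limma (825 at an unadjusted p under 0.05).

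Control livers differed between weeks, mainly through the 1-week arrays. Hccs, which attaches haem to cytochrome c, had a normalized log2 signal of 4.47 ± 0.09 (SD) in controls at 1 week, 2.60 ± 0.07 at 2 weeks and 2.44 ± 0.11 at 6 weeks. Utp6, a ribosome biogenesis factor, fell from 3.91 ± 0.15 to 2.10 ± 0.08 and 1.96 ± 0.12, Dnajc5, a chaperone of vesicles, from 2.84 ± 0.03 to 1.28 ± 0.04 and 1.07 ± 0.06, and the ribosomal protein gene Rpl36al from 2.86 ± 0.23 to 1.17 ± 0.05 and 0.89 ± 0.22. The pseudogene Pisd-ps3 rose from -4.50 ± 0.22 to -2.21 ± 0.05 and -2.35 ± 0.04. These are the 5 genes with the smallest adjusted p of 1596 that changed over the weeks in controls. Between controls, 1121 genes differed at 2 weeks from 1 week, 2212 at 6 weeks from 1 week and 0 at 6 weeks from 2 weeks by limma (1113 at an unadjusted p under 0.05). On the slide of weeks 1 and 2 alone 1168 genes changed, and week 6 lay on another slide. The 1596 became 388 without control replicate 1 at 1 week, 968 without CDAHFD replicate 1 at 2 weeks, 966 without CDAHFD replicate 2 at 2 weeks, 660 without control replicate 1 at 6 weeks and 666 without control replicate 2 at 6 weeks, and 737 with normexp.

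Within CDAHFD, 430 genes changed over the weeks, 39 between 1 and 2 weeks, 951 between 1 and 6 weeks and 2 between 2 and 6 weeks. The 430 became 125 without CDAHFD replicate 1 at 1 week, 21 without CDAHFD replicate 2 at 1 week, 199 without CDAHFD replicate 1 at 2 weeks, 224 without CDAHFD replicate 2 at 2 weeks, 248 without control replicate 1 at 6 weeks, 250 without control replicate 2 at 6 weeks and 831 without CDAHFD replicate 2 at 6 weeks. On the slide of weeks 1 and 2, 32 genes changed.

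**Figure D4:**
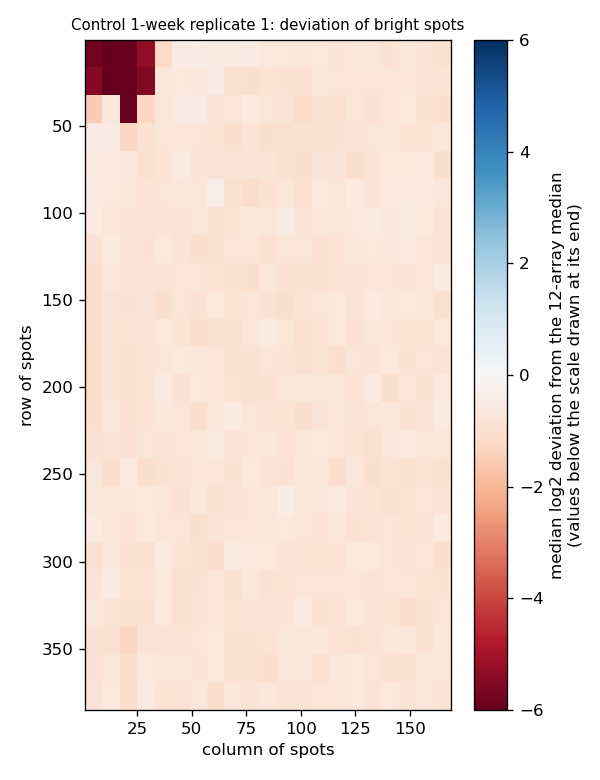
The map shows control replicate 1 at 1 week in blocks of spots by array row and column, coloured by the median log2 deviation of bright spots from the 12-array median. Of the 303 bright spots that read at least 8-fold below every other array, 286 lie in one corner.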

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

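All tests of explanations given in this part were chosen after the result they bear on was seen. The diet difference changed over the 3 weeks in 330 genes by limma's F test, and 747 genes differed between 6 weeks and 1 week.

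Among the 10 genes that the rule names for 6 weeks minus 1 week, log2 differences between the weekly diet differences were, for genes above background in each group, Ntrk2 (4.21 ± 0.53), Cib3 (3.68 ± 0.42), Serpina4-ps1 (-6.85 ± 1.20) and Dct (-3.69 ± 0.56). For genes below background in at least 1 group, the values are fitted and give no fold: Themis (4.82 ± 0.57), Syngr1 (4.20 ± 0.51), H19 (3.93 ± 0.66), Pdpr (-4.18 ± 0.83), Wif1 (-4.08 ± 0.99) and Gbp2b (-3.89 ± 0.84). H19 was not called with normexp (adjusted p = 0.0611), nor without CDAHFD replicate 2 at 1 week (adjusted p = 0.0525) or control replicate 1 or 2 at 6 weeks (adjusted p = 0.0621 and 0.0531). Pdpr was not called with normexp (adjusted p = 0.976), nor without CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0885 and 0.0601) or control replicate 1 at 6 weeks (adjusted p = 0.0917). Wif1 was not called with normexp, quantile normalization, no filter on dim probes, eBayes without trend or array weights (adjusted p = 0.718, 0.0575, 0.0587, 0.0583 and 0.0790), nor without control replicate 1 or 2 at 1 week (adjusted p = 0.0745 and 0.0745), CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0694 and 0.132), control replicate 1 or 2 at 2 weeks (adjusted p = 0.0541 and 0.0541), CDAHFD replicate 1 or 2 at 2 weeks (adjusted p = 0.0733 and 0.0729), control replicate 2 at 6 weeks (adjusted p = 0.0982) or CDAHFD replicate 1 or 2 at 6 weeks (adjusted p = 0.0698 and 0.0635). Gbp2b was not called with normexp (adjusted p = 0.504), nor without control replicate 1 at 1 week (adjusted p = 0.0777), CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0889 and 0.0913), CDAHFD replicate 1 or 2 at 2 weeks (adjusted p = 0.0553 and 0.0556), control replicate 1 or 2 at 6 weeks (adjusted p = 0.0594 and 0.0995) or CDAHFD replicate 2 at 6 weeks (adjusted p = 0.0574). Serpina4-ps1 was not called without CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0889 and 0.0892), CDAHFD replicate 1 or 2 at 2 weeks (adjusted p = 0.0590 and 0.0587) or control replicate 1 or 2 at 6 weeks (adjusted p = 0.0920 and 0.0982). Dct was not called without CDAHFD replicate 1 or 2 at 1 week (adjusted p = 0.0550 and 0.0510) or control replicate 1 at 6 weeks (adjusted p = 0.0543). Ntrk2 was at 4.88 or 3.53, Serpina4-ps1 at -5.82 or -7.88 and H19 at 3.14 or 4.72 without CDAHFD replicate 1 or 2 at 6 weeks. Pdpr was at -4.89 or -3.46 without control replicate 1 or 2 at 1 week. Wif1 was at -4.77 or -3.38 without CDAHFD replicate 1 or 2 at 1 week. Wif1 was at -5.26 or -2.89 without control replicate 1 or 2 at 6 weeks.

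For 13 of the 41 gene lists the diet difference at 6 weeks differed from that at 1 week by camera with the preset correlation, for 1 of them by fry and for 0 with an estimated correlation, where adjusted p ran from 0.313 to 0.759 and 2 of the 41 lists had an unadjusted p under 0.05. The median change over members was 0.93 for lipid-associated macrophage markers, 0.68 for macrophage and monocyte markers and 0.90 for liver tumour and oncofetal genes. It was 0.87 for female-biased liver genes, 0.74 for matrix remodelling, 0.65 for collagens and 0.64 for cholangiocyte markers. It was 0.49 for hepatic stellate cell markers and 0.34 for T and NK cell markers. For oxidative phosphorylation, lower at both weeks, the change was 0.29. Negative changes were -0.91 for cholesterol synthesis, -0.67 for circadian clock genes and -0.53 for liver sinusoidal endothelial cell markers. Cholesterol synthesis was at -0.58 both without control replicate 1 at 1 week and without control replicate 2 at 6 weeks, collagens were at 0.43 without CDAHFD replicate 2 at 1 week, and cholangiocyte markers at 0.40 without control replicate 2 at 1 week. The call ended for oxidative phosphorylation without CDAHFD replicate 1 at 6 weeks (0.16, adjusted p = 0.0884) and for the circadian clock without CDAHFD replicate 2 at 6 weeks (adjusted p = 0.0772). Female-biased genes lost it without control replicate 2 at 1 week (0.49, adjusted p = 0.0856), CDAHFD replicate 2 at 1 week (0.31, adjusted p = 0.0508) or CDAHFD replicate 1 at 6 weeks (0.20, adjusted p = 0.227), and were at 1.38 without control replicate 1 at 1 week and 1.60 without CDAHFD replicate 2 at 6 weeks. T and NK cell markers lost it without control replicate 1 at 1 week (adjusted p = 0.104), CDAHFD replicate 2 at 1 week (0.52, adjusted p = 0.0909), control replicate 1 or 2 at 2 weeks (adjusted p = 0.0520 and 0.0514), control replicate 1 at 6 weeks (adjusted p = 0.132) or CDAHFD replicate 1 at 6 weeks (0.16, adjusted p = 0.436), and were at 0.59 without control replicate 2 and 0.75 without CDAHFD replicate 2 at 6 weeks.

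Outside the genes tested, probes without a gene name gave 6485 features above background, of which 1731 changed at 6 weeks, 796 higher and 935 lower.

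In the controls 1596 genes changed between weeks, and the 1-week arrays stood apart. The dim corner of 1 array was argued against as the whole source, since 1711 genes changed with its blocks masked, though leaving the array out lowered the count to 388. Age in proportion to time and a difference between slides were argued against too, since 0 genes differed by limma between controls at 2 and 6 weeks (1113 at an unadjusted p under 0.05), 4 weeks of age and 1 slide apart, while 1121 differed between 1 and 2 weeks on the same slide. An age effect shared by both diets was argued against as the whole source, since as many genes, picked on 1 pair of control arrays for their change from 1 to 2 weeks, changed the same way by medians of 0.36 to 0.61 in the other control pair and -0.0311 to 0.18 in pairs of CDAHFD arrays. An effect of age in mice on chow alone, and differences in RNA or labelling of the 1-week controls, stay open and were not tested.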

How the results depend on the processing

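Each weekly diet comparison stayed within 1.5 times its count under median centring, quantile normalization, the percentile over all probes, array weights, the masked blocks and the mean of a gene's probes. Where counts moved further, the cause was not tested, except where fewer arrays or a stricter threshold set it. With normexp 3426 genes changed at 2 weeks, 3763 at 6 weeks and 737 between control weeks. Plain eBayes, without trend and robust, gave 163 for the change between weeks and 283 within CDAHFD. With unnamed probes included, 2943 features changed between control weeks. On slide 1, 32 changed within CDAHFD. A threshold of 2-fold left 2436, 2461 and 2775 genes at 1, 2 and 6 weeks, 2544 in the average, 445 for 6 weeks minus 1 week, 576 in controls and 233 within CDAHFD. Without the 1-week arrays limma called 0 genes for the change between weeks (825 at an unadjusted p under 0.05), 0 between control weeks (1064) and 1 within CDAHFD (1216). With 1 array left out, counts ran from 3072 to 6198 at 1 week, 3389 to 5805 at 2 weeks, 23 to 609 for the change between weeks, 129 to 941 for 6 weeks minus 1 week, 388 to 2123 in controls and 21 to 831 within CDAHFD. Replicate numbers did not pair the samples, as deviations of same-numbered arrays correlated at -0.14 to 0.22. A block for slide was not run, as it could not be fitted apart from the groups. With the replicate block, 69 genes changed between weeks and 367 for 6 weeks minus 1 week, where Cib3 (adjusted p = 0.0527), Dct (adjusted p = 0.0835), Serpina4-ps1 (adjusted p = 0.0887), Wif1 (adjusted p = 0.0662) and Gbp2b (adjusted p = 0.0516) were not called. Nor were Hsd3b5 at 2 weeks (adjusted p = 0.0685) and Cyp8b1 (adjusted p = 0.0536), Fn1 (adjusted p = 0.0521) and Pecam1 (adjusted p = 0.0669) at 6 weeks, while Dbp at 2 weeks (adjusted p = 0.0333) and Isg15 (adjusted p = 0.0237), Junb (adjusted p = 0.0489) and Srebf1 (adjusted p = 0.0403) at 6 weeks were called.

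With an estimated correlation camera called 0 lists per week, with the preset 27, 28 and 30, and fry 31, 30 and 33. List medians turned with normexp for neutrophil markers at 1 and 2 weeks (-0.12 and -0.14), T and NK cell markers at 1 week (-0.0197) and B and plasma cell markers at 1 week (-0.0806). They turned for acute phase and complement at 2 weeks with quantile normalization (0.45). Fatty acid oxidation at 6 weeks was at -0.63 without CDAHFD replicate 1 and 0.54 without replicate 2. As fitted, before the median of all genes was subtracted, genes turned with normexp at 1 week were Tnf (-0.27), Cd209a (-0.10) and Ms4a1 (-0.0933). Relative to that median Tnf stayed turned, at -0.07, while Cd209a was at 0.09 and Ms4a1 at 0.10. Quantile normalization turned Cox4i1 at 2 weeks (0.00644) and Fbp1 at 6 weeks (0.0269), also relative to the median. Against the controls of 2 and 6 weeks Alb at 1 week was at 0.0482 as fitted and -0.01 relative to the median. Of 5399 alternative named-gene values, 5225 kept direction and call status, 129 lost a call, 39 gained one and 6 turned as fitted. Of 2624 list values, 2429 kept both, 141 lost a call, 48 gained one and 6 turned. Leaving out 1 array gave 2820 of 5399 and 82 of 129, and the estimated correlation 85 of 141. Arrays of other weeks cannot move a weekly difference, inflating the share kept. Genes below background on a diet have only a bound there.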

Other observations

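Of the tests given in this part, those of bright probes, of oxidative phosphorylation and of a lower share of hepatocyte RNA were chosen after the result was seen. Stress and clock genes not described so far changed in part. Antioxidant (NRF2) response genes at 1 week had 10 members higher and 5 lower of 22 measured, or 10 and 6 adjusted over the list alone. The median lay at 0.33, with camera adjusted p = 0.558, and passed with normexp (adjusted p = 0.00535) and with no filter on dim probes (adjusted p = 0.0401). The quinone reductase Nqo1 (2.22 ± 0.41) and the haem oxygenase Hmox1 (1.87 ± 0.27) rose, Gclc (0.65 ± 0.20), which starts glutathione synthesis, was higher, and the carbonyl reductase Cbr3 (5.14 ± 0.35) rose. The unfolded protein and integrated stress response at 1 week had 5 members higher and 2 lower of 25 measured, or 5 and 2 adjusted over the list alone. As a list they had a median of -0.01, with camera adjusted p = 0.945. The chaperone Hspa5 (-0.36 ± 0.15) did not pass, and the transcription factors Ddit3 (1.37 ± 0.27) and Atf3 (4.22 ± 0.31) rose with Fgf21. Fatty acid oxidation and ketogenesis at 1 week had 3 members higher and 5 lower of 22 measured, or 3 and 4 adjusted over the list alone. The median of the list was -0.42, with camera adjusted p = 0.276. The carnitine transferase Cpt1a (0.72 ± 0.21) rose, Ppara (-0.23 ± 0.23) did not pass, and the mitochondrial thiolase Acaa2 (-0.93 ± 0.15) fell. Circadian clock genes at 2 weeks had 3 members higher and 3 lower of 17 measured, or 3 and 4 adjusted over the list alone. List members had a median of 0.16, with camera adjusted p = 0.924. The clock activators Arntl (-2.64 ± 0.39) and Clock (-1.06 ± 0.19) fell and Per2 (1.90 ± 0.37) rose, and Per1 (0.37 ± 0.29) and Dbp (0.83 ± 0.34) did not pass. Acaa2 was not called with quantile normalization (adjusted p = 0.904). Gclc was not called with the percentile over all probes or the controls of 2 and 6 weeks (adjusted p = 0.0687 and 0.134), nor without CDAHFD replicate 1 at 1 week (adjusted p = 0.0842). Cpt1a was not called with the controls of 2 and 6 weeks or the mean of a gene's probes (adjusted p = 0.0589 and 0.0597), nor without CDAHFD replicate 1 at 1 week (adjusted p = 0.0670). Hspa5 was called with the percentile over all probes (adjusted p = 0.0200). Dbp was called with quantile normalization, the mean of a gene's probes or array weights (adjusted p = 0.0430, 0.0320 and 0.0277), or without CDAHFD replicate 1 or 2 at 6 weeks (adjusted p = 0.00822 and 0.00817). Nqo1 was at 1.63 or 2.83 without control replicate 1 or 2 at 1 week. Against the controls of 2 and 6 weeks, Nqo1 was at 1.61. Another probe was at 0.46 for Hmox1.

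Markers of resident Kupffer cells, the macrophages of the liver sinusoids, at 2 weeks had 6 members higher and 1 lower of 18 measured, or 6 and 1 adjusted over the list alone. The median difference was 0.23, with camera adjusted p = 0.229, with calls under normexp (adjusted p = 0.0169), with no filter on dim probes (adjusted p = 0.0240) and without control replicate 2 at 2 weeks (adjusted p = 0.0462). Their anchors Clec4f (0.24 ± 0.24), Timd4 (0.15 ± 0.89) and Vsig4 (0.38 ± 0.25) did not pass, while Clec1b (1.31 ± 0.18) and Spic (1.40 ± 0.25) rose. Immediate early and handling response genes at 6 weeks had 10 members higher and 1 lower of 20 measured, or 10 and 1 adjusted over the list alone. Members had a median of 0.86, with camera adjusted p = 0.0317 and adjusted p = 0.386 with an estimated correlation, a call that ended without CDAHFD replicate 1 at 6 weeks (adjusted p = 0.225). Fos (2.41 ± 0.44) and Klf6 (2.89 ± 0.22) rose, and Egr1 (-0.21 ± 0.66) and Junb (-0.88 ± 0.41) did not pass. Adipocyte markers at 6 weeks had 1 members higher and 4 lower of 10 measured, or 1 and 4 adjusted over the list alone. In the median they were at -0.04, with camera adjusted p = 0.329, with Fabp4 (1.69 ± 0.17), also a macrophage gene, higher and Car3 (-1.62 ± 0.18), also a hepatocyte gene, lower. Pancreas and gut markers at 2 weeks had 1 members higher and 1 lower of 8 measured, or 1 and 1 adjusted over the list alone. Their median was 0.52, or 0.34 at bounds, with camera adjusted p = 0.854. Cela1 (0.84 ± 0.47, above background on 1 of 2 control arrays) and Amy2a5 (-0.20 ± 0.30) did not pass, the intestinal fatty acid binding protein Fabp2 (1.08 ± 0.13) rose and Ctrb1 (-1.32 ± 0.23) fell. Median, mean and test differed in sign for acute phase and complement at 1 and 2 weeks, the unfolded protein response at 1 and 6 weeks, adipocyte markers at 2 weeks, and fatty acid oxidation and Kupffer cell markers at 6 weeks. Junb was called with the percentile over all probes (adjusted p = 0.050). Vsig4 was called without control replicate 2 at 2 weeks (adjusted p = 0.0358). The other 2 probes were at 0.57 and 1.19 for Clec1b.

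The 8513 genes of the average over weeks were set against splits of the arrays made within each week. Of 100 splits drawn, only the real one called as many, and the next called 3906. This argues against chance only if replicates are separate mice. The 6 other splits with over 1000 genes kept the real diets on at least 8 of 12 arrays, and the remaining 93 called at most 17.

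Bright probes fell on balance at 6 weeks, and against random lists matched on signal the medians of hepatocyte identity, urea cycle, P450 and phase II genes still lay lower, with a median of -0.39 over the 4 lists and at most the 1.90th percentile, which argues against a scaling of bright probes as the whole cause. For oxidative phosphorylation, first tested with the other 4 and set apart after its value was seen, -0.12 at the 9.41th percentile does not decide. A lower share of hepatocyte RNA would lower hepatocyte genes alike, and of 68 urea cycle, P450 and phase II genes above background on both diets, 32 lay apart from their median by limma, 17 further down and 15 higher (in all 16 or 15 without control replicate 1 or 2 at 6 weeks), which argues against it as the whole cause for these lists. For hepatocyte identity, set apart after its value was seen, 0 of 23 lay apart by limma (2 at an unadjusted p under 0.05, and 1 called without CDAHFD replicate 2 at 6 weeks), so a lower share stays open there. A response of hepatocytes to the diet stays open and was not tested.

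Marker lists of macrophages, stellate cells and cholangiocytes were higher at 6 weeks. A scaling of dim probes was argued against, as the medians of the 3 lists lay 2.12, 1.21 and 1.13 above those of lists matched on signal, each at or above the 99.99th percentile. A lower share of hepatocytes would raise markers of other cell types alike. Leaving out shared genes, the sinusoidal endothelial median lay -2.87 from that of macrophages, which argues against this as the whole cause. The permutation p = 1e-05 (lowest possible, 2-sided) is over genes taken as independent, not arrays. More cells of the types that rose and more RNA of these genes per cell both stay open, and neither was tested.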
